A study of Homo sapiens with 12 samples.

How the data were processed

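The series holds 12 arrays of HepaRG and LX2 cells, each line grown alone or in coculture, with 3 replicates per group and 1 array per sample. The arrays lie on 2 slides of 6, and each slide holds arrays of all 4 groups. In both lines, alone replicates 1 and 2 lie on slide 1 and replicate 3 on slide 2. Coculture replicate 2 lies on slide 1 and replicates 1 and 3 on slide 2. The slide is thus partly confounded with coculture. Deviations from the group means correlated at a median of 0.212 between arrays of the same slide and -0.211 between arrays of different slides. Per the file headers, the intensity values are Cy3 signals extracted with Agilent Feature Extraction 10.7.1.1 (the submitters' processing notes name 10.7.3.1), as raw spot and local background medians and as a processed signal, from which background had been subtracted and a spatial trend removed within each array. The authors also deposited a table of log2 values with no stated method. From the values, that table was shifted per array and centred per probe, and across 15698 bright probes it correlated at 0.87 to 0.99 per array with the scanner values treated likewise.

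Each array had 62976 spots, of which 58717 were not controls. Spots marked as outliers were left out, replicate spots of a probe were averaged, and the processed signal was divided by the array's 75th percentile, set to at least 0.01 of it (-6.64 on the log2 scale) and taken as log2. Of 42405 probes, 24910 had a gene symbol, through the RefSeq accessions in the files and the reference gene table, and 17495 had none and were left out, as no name could be given to them. Of 24267 probes with an NM accession 23542 received a symbol. The headers name another genome build than the reference table, so no coordinates were used. For each of 19102 genes, of which 4835 had more than 1 probe, the probe with the highest mean over the arrays was kept, with those well above background on all arrays of some group preferred. Genes that mark sex are in the counts but were left out of all tables of genes.

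Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (files were read with version 1.17.8 of data.table), with all arrays in 1 model. The contrasts were: coculture minus alone in HepaRG, the same in LX2, the difference between these effects (HepaRG minus LX2), and HepaRG alone minus LX2 alone. A gene was tested where its probe was well above background on every array of at least 1 compared group, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. With all 12 arrays the model had 8 residual degrees of freedom. The correlation of the effects of both lines was computed across genes without a p-value.

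The tests, the filters, the 24 gene lists (466 genes, 459 with a probe) and the rule for naming genes were written before the data were examined. The rule names, for each coculture comparison, up to 8 called genes with the largest rise and up to 8 with the largest fall whose coculture arrays all lie on one side of the alone arrays, with a symbol that is not a locus or reading frame number. It also names 13 fixed genes, up to 4 called members of each list or the 2 furthest moved where none was called, and 5 genes per direction in the other contrasts. It was applied with all 12 arrays and again without LX2 coculture replicate 3. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with p-values adjusted over the lists of a contrast. A fold change against a group not well above background is given as a lower bound.

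Sensitivity was tested on simulated data, in which 200 genes were changed in each of 10 draws. With all arrays alike, 61.3% of HepaRG genes changed 1.5-fold, 78.5% of those changed 2-fold and 90.9% of those changed 4-fold were recovered. With 1 noisy LX2 array kept these shares were 0%, 0% and 19.9%, and with it left out 57.3%, 77.9% and 90.4%. In LX2 they were 49.6%, 72.7% and 87.7% with the array left out. With it left out, 8.02% of the HepaRG calls and 5.92% of the LX2 calls were genes that had not been changed, above the nominal 5%. The simulated noise was independent between genes and between arrays and held no slide effect, so the shares in the real data may differ.

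The results were recomputed with normexp background correction (offset 50), quantile normalization, median scaling, the authors' table, other filters and ways to combine probes, each comparison's arrays alone, a trended and robust variance, stricter thresholds, the slide or the replicate number as a block, and each replicate left out. Normexp was to use mean spot signals, which the files lack, so spot medians were used. Other floors (0.005 and 0.02), fits within each slide, the HepaRG and cell line contrasts without LX2 coculture replicate 3, every alternative on the 11 arrays, and the gene lists with median scaling, the authors' table or the slide as a block were added after the data had been seen.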

Results

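Gene expression was measured on 12 single-colour (Cy3) Agilent arrays from 2 human liver cell lines. HepaRG is a line that can take on hepatocyte-like properties, and LX2 is an immortalised line of hepatic stellate cells, the vitamin A storing cells that produce fibrous matrix in injured liver. Each line was grown alone or beside the other line, kept apart by a porous insert through which soluble molecules could pass, which made 4 groups of 3 replicates. The title of the series gives the question as the exchange of signals between hepatocytes and stellate cells. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. Changes are given as log2, coculture minus alone, with the standard error of the limma model after ±.

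LX2 coculture replicate 3 stood apart from the other 11 arrays. Its median signal was 8143 intensity units, against 115 to 171 on the others, and its negative control spots, which match no human transcript, had a median absolute deviation (MAD) of 759, against 2.24 to 3.84. Across genes it correlated at 0.303 to 0.364 with the other arrays, while arrays of the same group otherwise correlated at 0.985 to 0.997. With all 12 arrays in 1 model, as planned, 7 of 15444 genes were called in HepaRG at an adjusted p under 0.05 (5 higher, 2 lower), 0 of 15460 in LX2 and 0 of 16381 for the difference between the 2 coculture effects. In the same limma fits 243, 265 and 178 genes had an unadjusted p under 0.05. Each count is below the share of 0.05 of tested genes that would arise without any change, so it is no sign of one. The 5 higher genes in HepaRG were TMC5 (1.69), CA12 (1.43), KRT23 (1.25), CPNE5 (1.15) and IGFBP1 (1.12), and CHRM1 (-1.65) was among the lower ones. TMC5, KRT23, IGFBP1 and CHRM1 lay at the floor on all LX2 arrays. CA12 and CPNE5 had like values on all LX2 coculture arrays. The unlike LX2 array thus did not widen their spread, and these calls do not rank the HepaRG changes. With the slide or the replicate number as a block, or after normexp, quantile normalization or median scaling, 0 genes were called. Without the LX2 array, 1745 genes were called in HepaRG, 228 in LX2 and 436 for the difference. Leaving it out was planned for LX2 and for the difference only as 1 of the fits without single arrays. It was chosen for HepaRG and for the comparison of the lines after its values had been seen. The use of the 11 arrays as the main source of values was likewise chosen then, for all contrasts. A planned fit on the 6 HepaRG arrays alone called 799 genes (488 higher, 311 lower), and 819 (496 and 323) when the LX2 array was also absent from the steps before the fit. Of those 819 genes 713 were among the 1745. The values that follow come from the 11 arrays unless 12 are named. Their errors pool the spread of both lines, so a gene at the floor in 1 line has a narrower error in the other.

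**Figure D1:**
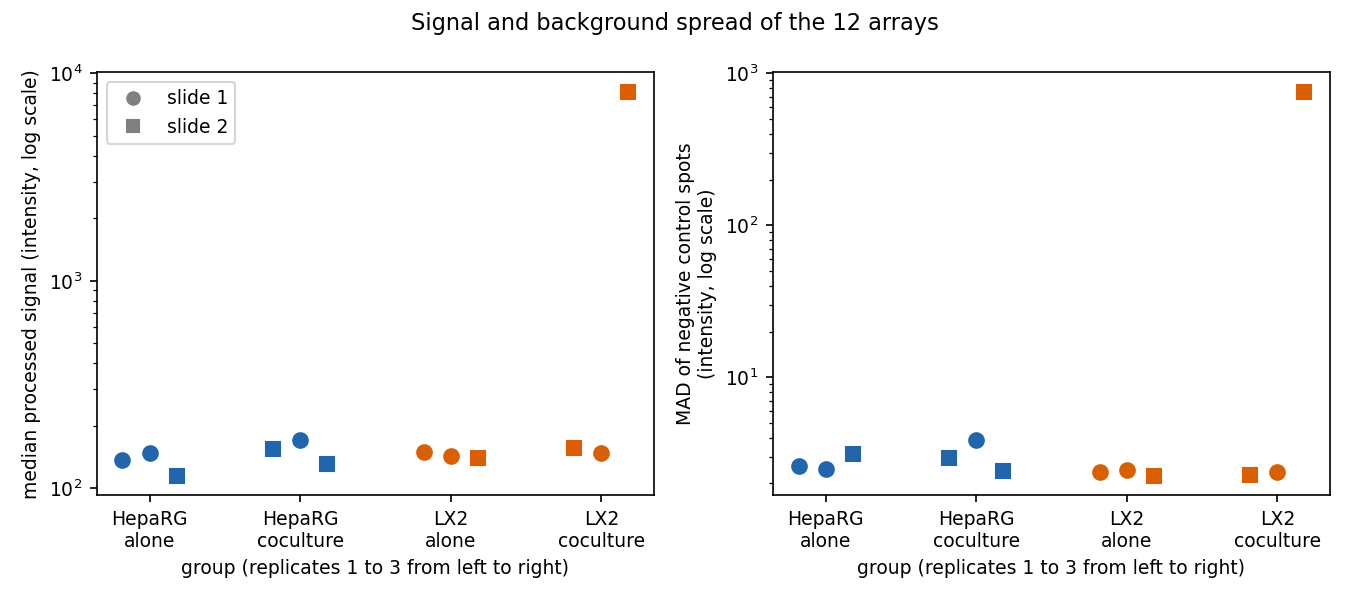
Median processed signal (left) and MAD of the negative control spots (right) of each array, both as intensity on log axes, by group, with circles for slide 1 and squares for slide 2. LX2 coculture replicate 3 lies at 8143 and 759, far above the other 11 arrays.

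In HepaRG the largest rise with coculture among called genes was that of CYP1A1, a cytochrome P450 that oxidises foreign aromatic compounds, at 3.95 ± 0.285 (15.5-fold, adjusted p = 0.000238, 3 arrays against 3). The next largest rises were those of the glycolytic enzyme ENO2 (2.69 ± 0.31), the mitochondrial protein gene COXFA4L3 (2.42 ± 0.205), the matricellular protein CCN5 (2.42 ± 0.117), the transmembrane collagen COL13A1 (2.16 ± 0.199), CFAP96 (2.00 ± 0.206), ZP1 (1.97 ± 0.304) and DENND2A (1.91 ± 0.177). The largest falls among called genes were smaller. They were those of the muscarinic acetylcholine receptor CHRM1 (-1.65 ± 0.0863), VLDLR-AS1 (-1.52), RANBP3L (-1.44), the surface antigen PSCA (-1.37), sarcolipin (SLN, -1.29), the tetraspanin TSPAN8 (-1.29) and AMTN (-1.29). LEFTY1, an inhibitor of Nodal signalling, was not well above background in coculture and was at least 2.46-fold lower there.

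Inflammatory genes rose together in HepaRG. Of 19 cytokines and chemokines tested, 11 rose and 0 fell (12 and 2 adjusted over the list alone), with a median change of 0.515 (0.291 after normexp). IL6 rose by 1.59 ± 0.136, IL1B by 1.21 ± 0.117, CCL20 by 1.06 ± 0.0943, CXCL8 by 0.95 ± 0.133, CCL2 by 0.62 ± 0.0397 and CXCL1 by 0.54 ± 0.0505. CCL7 was not well above background in HepaRG grown alone and was at least 2.78-fold higher in coculture. The list moved further than other genes by camera, with an adjusted p = 1.07e-06, and adjusted p = 0.00908 with an estimated correlation. Of 18 genes known as targets or regulators of the transcription factor NF-kB, 14 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.427. Among them were the early response gene IER3 (1.40 ± 0.0672), the adaptor TRAF1 (1.05 ± 0.0712), the pentraxin PTX3 (0.85 ± 0.0821) and the mitochondrial superoxide dismutase SOD2 (0.84 ± 0.104). The camera test gave an adjusted p = 2.72e-16, and adjusted p = 0.00908 with an estimated correlation. Of 24 acute phase and complement genes 17 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.576. Ceruloplasmin (CP) rose by 1.87 ± 0.146, serum amyloid SAA2 by 1.40 ± 0.134, serum amyloid P (APCS) by 1.08 ± 0.254 (not called with the slide as a block, adjusted p = 0.0541) and ITIH3 by 1.00 ± 0.137. SAA2 has a near-identical copy, SAA1, so its probe may read both. CRP was not called, though its scaled signals lay at -4.59, -5.29 and -4.55 alone and at -3.15, -2.98 and -3.25 in coculture. The error of CRP takes in its low LX2 signals, which ranged from -6.64 to -5.24. Here camera gave an adjusted p = 1.13e-16, and adjusted p = 0.0566 with an estimated correlation.

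Genes that low oxygen induces, together with glycolytic enzymes, also rose in HepaRG. Of 20 tested, 15 rose and 0 fell, over all genes and adjusted over the list alone, with a median of 0.633. Besides ENO2, these were led by NDRG1 (1.62 ± 0.161), the glycolytic aldolase ALDOC (1.34 ± 0.12) and the mitophagy receptor BNIP3 (1.20 ± 0.114). The adjusted p of camera was 7.68e-13, and adjusted p = 0.0455 with an estimated correlation. The blood vessel growth factor VEGFA changed by 0.24 ± 0.0932, which was not called (adjusted p = 0.149). Of 15 angiogenic factors 3 rose and 2 fell (3 and 3 adjusted over the list alone), among them ANGPTL4 (0.86), VEGFC (0.58), VEGFB (0.36) and adrenomedullin ADM (-0.32), of which VEGFB and ADM were not called with the slide as a block (adjusted p = 0.0632 and 0.0589), and the list was not called (adjusted p = 0.703).

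Of 16 matrix proteases and inhibitors 7 rose and 1 fell (7 and 2 adjusted over the list alone). The collagenase MMP1 rose by 1.14 ± 0.225, MMP10 by 0.72 and MMP3 by 0.60, while MMP9 stood at -0.14 ± 0.0935 and was not called. That list passed camera with an adjusted p = 0.0244, but adjusted p = 0.373 with an estimated correlation. It was not called without HepaRG alone replicate 3 (adjusted p = 0.123), coculture replicate 1 (0.0719) or coculture replicate 3 (0.0533). Nor was it called after quantile normalization (0.0643, median 0.174) or from the authors' table (0.0788). Its median of 0.242 was 0.139 after normexp. The list of oxidative stress genes and metallothioneins gave the same values, 0.0244 and an adjusted p = 0.373 with an estimated correlation. It was not called without HepaRG alone replicate 2 (0.0648) or coculture replicate 1 (0.101), or with the slide as a block. Of its 15 genes 5 rose and 0 fell (6 and 2 adjusted over the list alone), and the 4 largest rises were in metal-binding metallothioneins, MT1X (1.06), MT1H (0.91), MT1E (0.77) and MT1A (0.73), whose probes may read each other's transcripts. Of 9 leukocyte and Kupffer cell markers 3 rose and 0 fell (4 and 0 adjusted over the list alone): the scavenger receptor MARCO (1.01), the lipopolysaccharide co-receptor CD14 (0.67) and the lysosomal protein CD68 (0.32), with an adjusted p = 0.00629, and adjusted p = 0.106 with an estimated correlation. The median of these markers, 0.316, was 0.0779 after normexp, and 0.175 after quantile normalization, where the list was not called (adjusted p = 0.057). Of 26 cell cycle genes 6 fell and 0 rose (8 and 0 adjusted over the list alone). These included the replication helicase subunits MCM5 (-0.35), MCM4 (-0.31) and MCM2 (-0.27) and the transcription factor E2F1 (-0.33). Their median was -0.15 (-0.0855 without HepaRG coculture replicate 3), with an adjusted p = 3.55e-05, and adjusted p = 0.395 with an estimated correlation.

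Some markers of the hepatocyte and stellate cell types were called in HepaRG, where 11.3% of all tested genes were called. Of 24 hepatocyte genes 3 rose and 0 fell, the same as adjusted over the list alone. They were prothrombin F2 (0.39), F9 (0.34) and apolipoprotein APOB (0.32), and albumin (ALB) stood at -0.24 ± 0.627 without a call. The error of ALB takes in its low LX2 signals, which ranged from -6.11 to -3.54. F2, F9 and APOB lay at the floor on all LX2 arrays used, which narrows their errors. Which hepatocyte genes were called thus depends in part on their LX2 signals. Its HepaRG signals lay at 8.44 to 8.75 alone and at 8.18 to 8.5 in coculture. In drug metabolism 4 of 22 genes rose and 4 fell (4 and 5 adjusted over the list alone). After CYP1A1 came CYP1B1 (1.04), CYP1A2 (0.92) and ADH4 (0.67), and CYP3A4 stood at -0.64 ± 0.401 without a call. In bile acid metabolism 2 of 14 rose and 3 fell (4 and 3 adjusted over the list alone), with the transporter subunit SLC51A at 1.81, CYP7A1, the rate-limiting enzyme of bile acid synthesis, at 0.37 and the conjugating enzyme BAAT at -0.51. NR0B2 was not called, though its scaled signals lay at -2.35, -2.28 and -2.34 alone and at -3.96, -3.3 and -3.63 in coculture. Those of CYP3A4 lay at -2.38 to -1.99 alone and at -3.12 to -2.42 in coculture. The errors of NR0B2 and CYP3A4 also take in their low LX2 signals, from -6.64 to -4.08 and from -6.17 to -4.48. Of 13 stellate cell markers 1 rose, IGFBP3 (1.29), and 2 fell, calponin CNN1 (-0.62) and S100A4 (-0.36), against 2 and 2 adjusted over the list alone, while ACTA2 (-0.03, and 0.02 after normexp) and COL1A1 (-0.31) were not called. Of 12 biliary and progenitor markers 3 rose and 2 fell (4 and 3 adjusted over the list alone), with MUC1 at 1.28, KRT23 at 1.25, SPP1 at -0.82 and SOX9 at -0.64. The 2 MUC1 probes gave 0.312 and 1.28. The angiopoietin receptor TEK, at the floor on 2 of 3 arrays of cells grown alone, was the only 1 of 6 endothelial markers called, also adjusted over the list alone.

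Among the other lists in HepaRG, 3 of 23 growth factors tested rose and 2 fell (6 and 3 adjusted over the list alone), led by the epidermal growth factor receptor ligands EREG (1.48) and AREG (0.88), with IGF1 at 0.62 and FGF1 at -0.35. Extracellular matrix genes went both ways, with 4 of 24 higher and 5 lower (6 and 5 adjusted over the list alone), such as THBS2 (1.18), DCN (0.79) and COL5A1 (0.60) against POSTN (-0.92). TGF-beta targets had 5 of 19 higher and 4 lower (5 and 7 adjusted over the list alone), with TGFBI at 0.85, LTBP2 at 0.78, ID1 at 0.73 and TGFB2 at 0.48, and TGFB1 itself at -0.03 without a call. Interferon response genes had 4 of 19 higher and 2 lower, also adjusted over the list alone, with MX2 at 0.96 and IFI44L at 0.43 against IFIT1 (-0.54) and IFIT2 (-0.50). Of 17 immediate early and MAPK targets 4 rose and 0 fell (5 and 3 adjusted over the list alone), namely DUSP6 (0.60), MYC (0.57), DUSP5 (0.57) and EGR1 (0.42). Of 23 cholesterol and fatty acid synthesis genes 3 rose and 0 fell (5 and 1 adjusted over the list alone), SQLE (0.19) among them, which was not called with the slide as a block (adjusted p = 0.0806). Unfolded protein response genes gave 1 higher, the chaperone HSPA5 (0.38), and 1 lower of 19 (2 and 1 adjusted over the list alone), ATF3 (-0.34), whose 4 probes ranged from -0.456 to 0.0485. Epithelial to mesenchymal transition genes gave 1 higher and 2 lower of 14 (2 and 3 adjusted over the list alone), TWIST2 (0.23) against the cadherins CDH2 (-0.24) and CDH1 (-0.18). Of 12 housekeeping genes 4 were higher, also adjusted over the list alone, led by the glycolytic enzyme GAPDH (0.56). Apart from the 8 lists with a camera value under 0.05 given above, the adjusted p lay between 0.117 and 0.98. For the extracellular matrix, growth factor, drug metabolism, bile acid, stellate cell, biliary, TGF-beta and interferon lists the median was below 0 and the mean above 0.

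Of the 1745 genes called in HepaRG 1003 were higher and 742 lower, and 117 changed at least 2-fold (103 higher, 14 lower). The calls numbered 200 under median scaling (135 higher, 65 lower), 710 after normexp background correction (490 and 220), 1245 after quantile normalization (771 and 474) and 758 from the authors' table (552 and 206). With the replicate number as a block 821 were called (509 higher, 312 lower). With the slide as a block 1659 genes were called (969 higher, 690 lower). Within each slide 1 of the 2 HepaRG groups held a single array, so calls there are left out. Across all tested genes the changes on the slides correlated at 0.321. On slides 1 and 2 the medians of the cytokine list were 0.555 and 0.542, of the NF-kB list 0.419 and 0.438, of the acute phase list 0.653 and 0.468 and of the hypoxia list 0.618 and 0.611, and with the slide as a block 0.483, 0.407, 0.584 and 0.627. With all 12 arrays the same 4 lists passed camera, with adjusted p = 1.58e-07, 1.32e-10, 3.86e-13 and 3.79e-10, and with an estimated correlation the adjusted p = 0.00736, 0.114, 0.114 and 0.233, and limma called 0 of their genes.

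In LX2, the genes of the low oxygen response rose most with coculture. Of 20 hypoxia and glycolysis genes 9 rose and 0 fell (16 and 0 adjusted over the list alone), all 20 had positive changes, and the median was 0.646. The pH-regulating carbonic anhydrase CA9 rose by 2.04 ± 0.226 (4.12-fold, adjusted p = 0.00762, 2 coculture arrays against 3), BNIP3 by 1.00 ± 0.128, ALDOC by 0.96 ± 0.134 and the glycolytic kinase PGK1 by 0.78 ± 0.0755. The adjusted p of camera was 1.56e-24, and adjusted p = 0.0156 with an estimated correlation. VEGFA rose by 0.92 ± 0.104 and ANGPTL4 by 0.57, the 2 genes called of 16 angiogenic factors (3 and 0 adjusted over the list alone), a list with an adjusted p = 0.0291, and adjusted p = 0.197 with an estimated correlation. Its adjusted p was 0.241 without LX2 coculture replicate 2. Its median of 0.115 was 0.072 without that array and 0.0685 without LX2 alone replicate 3. It was 0.068 after normexp and 0.191 under median scaling. Of 17 matrix proteases and inhibitors 3 rose and 0 fell (6 and 1 adjusted over the list alone), the collagen crosslinking enzyme LOX (0.84 ± 0.0191), the gelatinase MMP9 (0.68 ± 0.105) and the urokinase receptor PLAUR (0.35), with a median of 0.104 (0.16 without LX2 alone replicate 3, 0.18 under median scaling) and an adjusted p = 0.00593, and adjusted p = 0.197 with an estimated correlation. Other large rises were those of the phospholipase PLA2G4D, at the floor on 2 of 3 arrays of cells grown alone, the carbonic anhydrase CA12 (1.35 ± 0.0974), the peptide hormone apelin (APLN, 1.23 ± 0.136), the elongation factor EEF1A2 (1.12 ± 0.158), WFDC10B (1.05 ± 0.181) and the gap junction gene GJB2 (0.99 ± 0.0912). The largest falls among called genes were those of ASPA (-0.96), PRODH (-0.94), KLHL30 (-0.90), IL27 (-0.87), netrin NTN1 (-0.86), the Notch target HES1 (-0.81) and SRGAP3 (-0.77), and BLNK, not well above background in coculture, was at least 1.87-fold lower. WFDC10B and HES1 (adjusted p = 0.0675 each), BLNK (adjusted p = 0.0571) and PLAUR (adjusted p = 0.0801) were not called with the slide as a block. CA9 lay at the floor on 1 of 3 arrays of cells grown alone, so its size depends on it.

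Inflammatory genes did not rise as a group in LX2. Of 21 cytokines and chemokines 1 rose, CXCL6 (0.41 ± 0.0744, not called with the slide as a block, adjusted p = 0.0801), and 2 fell, CXCL1 (-0.75 ± 0.0565) and CCL2 (-0.35), against 3 and 4 adjusted over the list alone. IL6 stood at 0.14 ± 0.152, CXCL8 at -0.35 ± 0.148 and IL1B at -0.03 ± 0.131, all without a call, and the list had a median of -0.0346 (0.0414 under median scaling) and an adjusted p = 0.168. Of 18 NF-kB targets 0 were called by limma (3 and 2 adjusted over the list alone), where SOD2 (0.46) and BCL3 (0.46) moved furthest, and of 20 acute phase and complement genes 1 rose, the cytokine signalling inhibitor SOCS3 (0.94 ± 0.0531), also adjusted over the list alone, with adjusted p = 0.2 and 0.135. Interferon response genes shifted down by camera (adjusted p = 0.000384, but adjusted p = 0.0647 with an estimated correlation), with ISG15 (-0.67 ± 0.109), IFIT2 (-0.56) and IFIT3 (-0.54) lower of 19 (1 higher and 6 lower adjusted over the list alone). The interferon median of -0.0823 was -0.00625 under median scaling. With the slide as a block ISG15 (adjusted p = 0.0572) and IFIT3 (adjusted p = 0.0533) were not called. Of 18 immediate early and MAPK targets EGR1 (-0.71 ± 0.095) and EGR3, at the floor on both coculture arrays, fell and 0 rose (1 higher and 3 lower adjusted over the list alone), with a median of -0.154 (-0.0879 without LX2 coculture replicate 1, -0.0776 under median scaling) and an adjusted p = 0.002, and adjusted p = 0.197 with an estimated correlation. Of 23 growth factors FGF1 rose (0.49) and the stress-induced GDF15 fell (-0.40), against 1 and 3 adjusted over the list alone and neither called with the slide as a block (adjusted p = 0.074 and 0.0635), with a median of -0.134 (-0.0584 under median scaling) and an adjusted p = 0.000846, but adjusted p = 0.0667 with an estimated correlation. All 23 cholesterol and fatty acid synthesis genes had positive changes, with a median of 0.138 (0.214 under median scaling), largest in MSMO1 (0.34) and INSIG1 (0.33), 0 of them called and 2 higher adjusted over the list alone (adjusted p = 1.67e-05, but adjusted p = 0.0647 with an estimated correlation).

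Among the markers of activated stellate cells, ACTA2 and COL1A1 were not called in LX2. Smooth muscle actin ACTA2 stood at -0.17 ± 0.035 (adjusted p = 0.0717), COL1A1 at 0.08 ± 0.165, albumin (ALB) at -0.49, CYP3A4 at -0.20, TGFB1 at 0.18 ± 0.0769 and MMP1 at 0.15 ± 0.251. Of 18 stellate cell markers THY1 (0.19) was called, with 2 higher and 1 lower adjusted over the list alone, and of 26 extracellular matrix genes THBS2 (0.77), the same as adjusted over the list alone. TGF-beta targets had 3 of 20 higher and 1 lower (4 and 3 adjusted over the list alone), TGFBI (0.42), SMAD6 (0.40) and TGIF1 (0.22) against PMEPA1 (-0.41). Of 16 oxidative stress and metallothionein genes SLC7A11 (-0.56, not called with the slide as a block, adjusted p = 0.0637) and MT1F (-0.33) fell (1 higher and 5 lower adjusted over the list alone), with a median of -0.0325 (0.0435 under median scaling, -0.0694 after quantile normalization, -0.0138 after normexp, 0.0398 and 0.00156 without LX2 alone or coculture replicate 1, with no call, and -0.119 and -0.0737 without LX2 alone replicate 3 or coculture replicate 2) and an adjusted p = 0.0321, and adjusted p = 0.225 with an estimated correlation. This list was not called under median scaling (adjusted p = 0.129), after normexp (0.139) or from the authors' table (0.0947). Housekeeping genes had the same adjusted p = 0.0321, with adjusted p = 0.204 with an estimated correlation, a median of 0.0689 and 0 of 12 called (1 adjusted over the list alone), the furthest being GAPDH (0.35) and PPIA (0.29). The housekeeping list was not called without LX2 alone replicate 1 (adjusted p = 0.0721) or 3 (0.0818) or coculture replicate 2 (0.12). Its median was 0.111 without LX2 alone replicate 2 and 0.121 without coculture replicate 1, 0.0374 after quantile normalization, and 0.145 under median scaling, where it was not called (adjusted p = 0.155). Single calls were apolipoprotein APOA1 (0.66) of 11 hepatocyte genes, UGT2B7 (-0.69) of 15 drug metabolism genes, ASNS (-0.38) of 19 unfolded protein response genes and CD14 (0.37) of 9 leukocyte and Kupffer markers, and adjusted over the list alone these lists gave 1 higher, 1 higher and 1 lower, 2 lower, and 1 higher. Of 7 endothelial markers TIE1 (0.75) rose and KDR (-0.66) fell, also adjusted over the list alone. None of 8 bile acid, 26 cell cycle, 11 biliary and 13 epithelial to mesenchymal transition genes was called, and 2 biliary genes were higher adjusted over the list alone, 0 in the other 3 lists. Among the furthest moved were NR0B2 (-0.86) and SLC10A1 (0.16), CDK1 and TOP2A (0.17 each), MUC1 (0.72, adjusted p = 0.0572), and CLDN1 and SNAI1 (0.22 each), of which SLC10A1 and CLDN1 changed sign after normexp. The lists not given an adjusted p here lay between 0.0708 and 0.97, and in the extracellular matrix, biliary, endothelial and leukocyte lists the median was below 0 and the mean above 0.

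**Figure D2:**
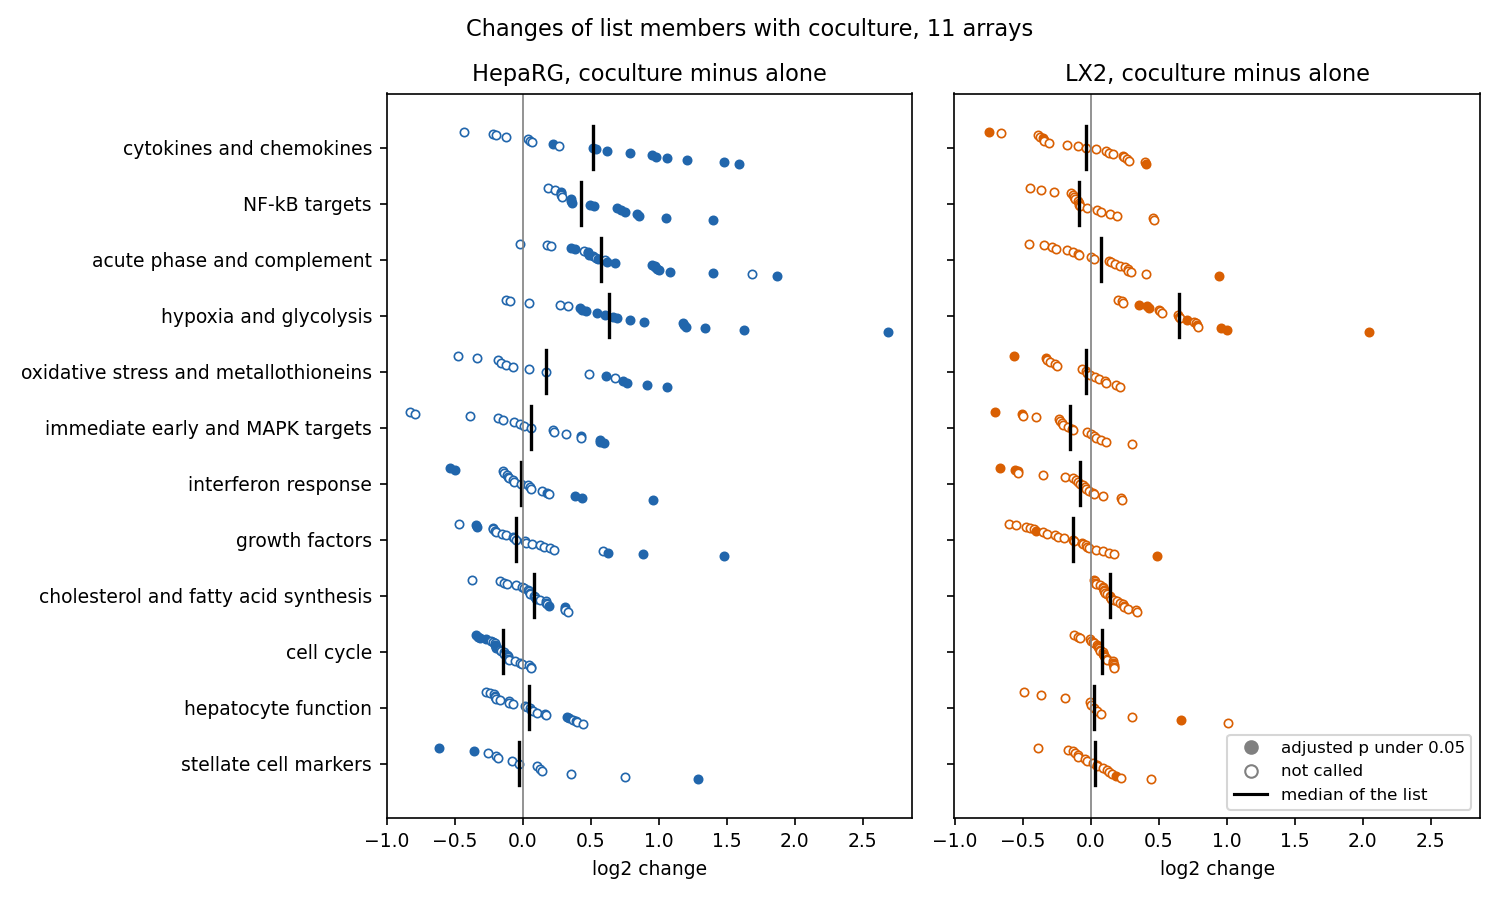
Log2 change with coculture of each tested member of 12 gene lists in HepaRG (left) and LX2 (right), from 11 arrays, with filled points for an adjusted p under 0.05, open points for genes not called and black lines at the list medians. The hypoxia and glycolysis medians lie at 0.633 and 0.646, while the cytokine medians lie at 0.515 in HepaRG (0.291 after normexp) and -0.0346 in LX2 (0.0414 under median scaling).

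The 228 genes called in LX2 (140 higher, 88 lower, of 15611) rest on 5 arrays. The count was 143 without LX2 alone replicate 1, 105 without coculture replicate 1, 84 without coculture replicate 2, and 155 and 242 without LX2 alone replicates 2 and 3. Of the 228 genes 7 changed at least 2-fold, all higher. With other processing the calls were 6 under median scaling (all higher) and 42 after normexp (35 higher, 7 lower). They were 122 after quantile normalization (75 and 47) and 39 from the authors' table (23 and 16). The 5 LX2 arrays fitted alone gave 17, of which 9 were among the 228. With the replicate number as a block limma called 0 genes. With the slide as a block 212 genes were called (127 higher, 85 lower). Calls within a slide are left out, since some LX2 groups there held a single array. Across all tested genes the changes on the slides correlated at 0.216. The hypoxia median was 0.683 on slide 1, 0.606 on slide 2 and 0.643 with the slide as a block. With all 12 arrays limma called 0 members of any list in LX2, and no list kept a camera call with an estimated correlation, where the lowest adjusted p = 0.686.

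The difference between the coculture effects of the 2 lines was called for 436 of 16455 genes, 236 with the higher change in HepaRG and 200 with the higher change in LX2. CYP1A1 differed by 3.98 ± 0.427, CCN5 by 2.42 ± 0.176, COXFA4L3 by 2.08 ± 0.308, CP by 1.96 ± 0.22 and the interleukin 33 receptor IL1RL1 by 1.84 ± 0.204, all higher in HepaRG. The differences of LEFTY1 (-1.84), CHRM1 (-1.65), PSCA (-1.47), RIPOR3 (-1.36) and TSPAN8 (-1.29) went the other way. CHRM1 and TSPAN8 were not well above background in LX2 and lay at the floor on all LX2 arrays used. A fall there could not be seen, so their differences only repeat the HepaRG changes. The chemokines CXCL1 and CCL2 were called in opposite directions, with changes of 0.54 and 0.62 in HepaRG against -0.75 and -0.35 in LX2, and the differences of 1.29 and 0.97 were called (adjusted p = 0.000494 and 0.000518). NF-kB targets had the lowest camera p-value of the lists, with 9 of 19 genes higher in HepaRG (15 adjusted over the list alone), a median difference of 0.477 and an adjusted p = 3.19e-18, and adjusted p = 0.00311 with an estimated correlation. Cytokines and chemokines had 8 of 22 higher (9 higher and 1 lower adjusted over the list alone) and a median difference of 0.704 (0.329 without HepaRG coculture replicate 2, 0.235 after normexp, 0.35 after quantile normalization), with an adjusted p = 1.21e-07, and adjusted p = 0.00519 with an estimated correlation. Acute phase and complement genes had 8 of 24 higher (12 adjusted over the list alone) and a median of 0.549, with an adjusted p = 3.22e-14, but adjusted p = 0.0916 with an estimated correlation. Of 21 hypoxia and glycolysis genes 0 were called by limma (3 higher and 3 lower adjusted over the list alone), with a median of 0.0447 (-0.0716 under median scaling) and an adjusted p = 0.911.

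The count of 436 was 250 without HepaRG alone replicate 1, 229 and 238 without LX2 alone replicates 1 and 2, and 190 and 182 without LX2 coculture replicates 1 and 2. It was 19 under median scaling (10 higher, 9 lower), which moved the median of all genes from 0.00093 to -0.11, 100 after normexp (82 and 18), 179 after quantile normalization (119 and 60) and 89 from the authors' table (67 and 22). With the replicate number as a block limma called 0. With the slide as a block 389 were called (214 and 175). Calls within a slide are left out, since some groups there held a single array. Across all tested genes the differences on the slides correlated at 0.215. On slides 1 and 2 the median difference was 0.418 and 0.555 for NF-kB targets, 0.761 and 0.316 for cytokines and 0.499 and 0.484 for acute phase genes, and with the block 0.477, 0.746 and 0.538.

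**Figure D3:**
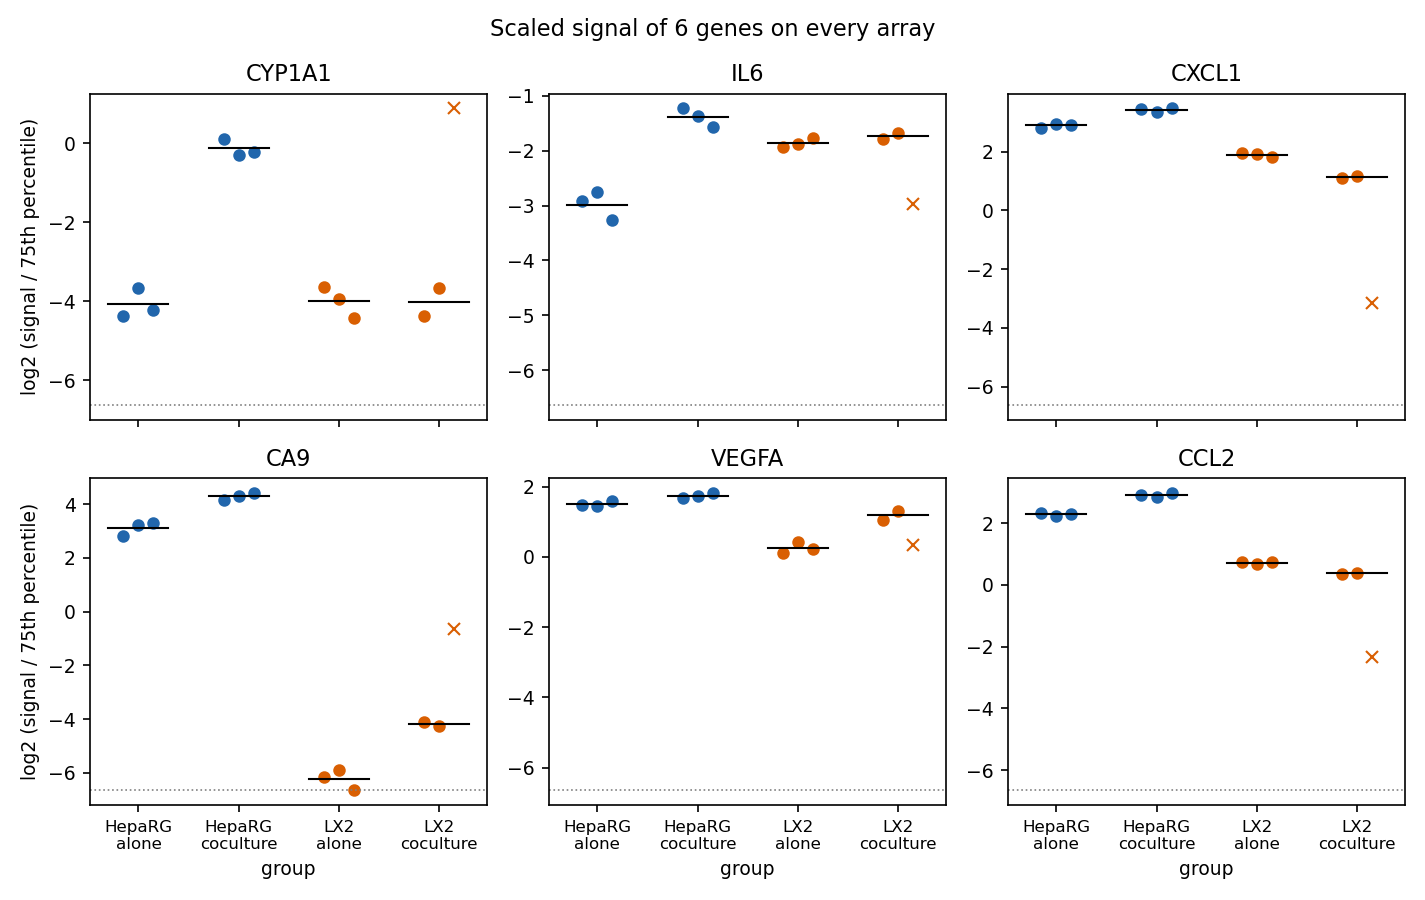
Signal of 6 genes on each of the 12 arrays, as log2 of the signal over the array's 75th percentile, by group, with points for arrays, black lines for group means, a cross for LX2 coculture replicate 3, which is outside the mean, and a dotted line at the floor of -6.64. CYP1A1 and IL6 changed by 3.95 and 1.59 in HepaRG, CA9 and VEGFA by 2.04 and 0.92 in LX2, and CXCL1 and CCL2 moved in opposite directions in the 2 lines.

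Among the 14598 genes tested in both lines, 59 were called higher in both, where independent lists of that size would share 6.5, and 26 were called lower in both, against 3.17. The genes named from these overlaps were chosen after their values had been seen. The 59 included 7 hypoxia and glycolysis genes, among them BNIP3, CA9, ALDOC and PGK1, and also CA12, ANGPTL4, SOCS3, CD14, THBS2 and TGFBI. IFIT2, UGT2B7 and RANBP3L were among the 26. Opposite calls were made for 9 genes higher in HepaRG and lower in LX2, against 4.54, and for 3 genes lower in HepaRG and higher in LX2, against 4.54. Across 14871 genes, which are not independent, the changes of the 2 lines correlated at r = 0.198 (Spearman 0.195), at 0.197 with the slide as a block and at 0.276 with the replicate number as a block. That value was 0.0412 without LX2 coculture replicate 1 and 0.107 without LX2 alone replicate 1. With 12 arrays it was 0.165, -0.132 with the slide as a block, and -0.0787 without HepaRG coculture replicate 2.

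Grown alone, the lines differed in most genes tested. HepaRG had far higher levels of liver plasma proteins, with transthyretin (TTR) higher by 14.0 ± 0.454 and albumin (ALB) by 13.2 ± 0.627. The transport proteins APOH and AMBP, at the floor on most or all LX2 arrays, were also called higher. Fibrinogen gamma (FGG), not well above background in LX2, was at least 7400-fold higher in HepaRG. LX2 had higher levels of the ubiquitin hydrolase UCHL1, at the floor on most HepaRG arrays, the calcium binding protein S100A6 (-12.2 ± 0.274) and the glutathione transferase GSTP1 (-11.2 ± 0.177). BEX1 and the myosin light chain MYL9, not well above background in HepaRG, were at least 2940-fold and at least 2550-fold higher in LX2. The line with the lower level lay near the floor for most of these genes, so the sizes depend on it. With 12 arrays 4251 of 16143 genes were called (2075 higher in HepaRG, 2176 higher in LX2), and with 11 arrays 12013 of 16144 (5425 and 6588), of which 6066 differed at least 2-fold. With the slide as a block 12258 were called, 11432 on slide 1 and 6543 on slide 2, and the changes on the 2 slides correlated at 0.982 across genes.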

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

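In this part the counts of other splits of the arrays were planned. The tests of explanations, the use of 11 arrays for the main values, and the fits within slides were chosen after the results had been seen.

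With 11 arrays, the difference between the coculture effects of the lines was called for 436 genes. By gene, the differences were 3.98 for CYP1A1, 2.42 for CCN5, 2.08 for COXFA4L3, 1.96 for CP and 1.84 for IL1RL1, and -1.84 for LEFTY1, -1.65 for CHRM1, -1.47 for PSCA, -1.36 for RIPOR3 and -1.29 for TSPAN8, with adjusted p from 0.000385 to 0.0176, and the size for LEFTY1, at the floor in HepaRG coculture, depends on the floor. CHRM1 and TSPAN8 lay at the floor on all LX2 arrays used, so their differences only repeat the HepaRG changes. By list, the median differences were 0.704 for cytokines and chemokines (0.329 without HepaRG coculture replicate 2), 0.477 for NF-kB targets, 0.549 for acute phase and complement genes, 0.374 for oxidative stress genes and metallothioneins, 0.25 for leukocyte and Kupffer markers (0.165 and 0.173 without HepaRG coculture replicate 2 or LX2 alone replicate 1, with no call, and 0.407 without LX2 coculture replicate 2), 0.246 for growth factors, 0.231 for immediate early and MAPK targets, 0.131 for interferon response genes and -0.232 for cell cycle genes (0.059 and -0.142 without HepaRG coculture replicate 3). Each list passed camera at the preset correlation, and with an estimated correlation the cytokine and NF-kB lists passed and the other lists had adjusted p from 0.0916 to 0.212. Without single arrays the count lay between 182 (without LX2 coculture replicate 2) and 415, and it was 190 without LX2 coculture replicate 1, 229 and 238 without LX2 alone replicates 1 and 2 and 250 without HepaRG alone replicate 1. With all 12 arrays 0 genes were called by limma (178 at an unadjusted p under 0.05). Each of 100 splits gave at least as many, at most 2, which a real count of 0 makes certain, so the splits decide nothing here.

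The splits of 3 arrays against 3 are too few for a share under 0.05. In HepaRG the real split called 1745 genes and the others at most 6 with 11 arrays, and 7 and 0 with 12, where 1 of 10 splits gave as many. In LX2 with 12 arrays the real split and the others called 0, so all 10 gave as many, which a real count of 0 makes certain. Between the lines the real split called 12013 and 4251 genes with 11 and 12 arrays and the others 0.

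The rise of cytokine, NF-kB and acute phase genes in HepaRG covered 42 of 61 members tested, with 0 called lower. RNA carried over from LX2 cells is argued against by genes abundant in LX2 and not well above background in HepaRG alone, which changed by a median of 0.0684 in HepaRG coculture, and 100% of the 42 members needed a larger share of LX2 RNA than the upper quartile of 0.18% that genes abundant in LX2 showed. HepaRG coculture replicate 2 had a raised dim signal, with a 25th percentile of 40.5. The 10 other arrays apart from LX2 coculture replicate 3 had 12.7 to 18.5. Without HepaRG coculture replicate 2, 85.7% of the members were still called. Slides 1 and 2 gave medians of 0.62 and 0.44. That array is the only HepaRG coculture array on slide 1, so the median of 0.62 rests on it. Without it all HepaRG coculture arrays lie on slide 2, so the checks of this array and of the slides are not independent. A response to signals from LX2 cells may account for the rise, but so may the culture with an insert, since no group had an empty insert, and this was not tested.

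LX2 coculture replicate 3 had negative control spots whose MAD was 197 times the widest of the other arrays. Those spots match no human transcript, so the value of 197 argues against a response of the LX2 cells and is consistent with a fault of the array or its hybridisation. A swapped label is argued against by its highest correlation with any other array, 0.364. Which step failed stays open.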

How the results depend on the processing

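Leaving out LX2 coculture replicate 3 was planned for LX2, the difference and the correlation, as 1 of the fits without single arrays. Leaving it out for HepaRG and the cell lines, the other settings on 11 arrays, other floors and fits within slides were added after the data had been seen. The causes of changes were not tested, except that stricter thresholds call fewer genes by construction. With 12 arrays the 7 HepaRG calls became 0 after normexp, quantile, median scaling, the authors' table, probes well above background on all arrays, a trended robust variance, the replicate block, the slide block and an adjusted p under 0.01, 3 without the filter and by probe, 1 and 19 with floors of 0.005 and 0.02, 799 from the HepaRG arrays alone, and 0 to 1745 without single arrays (0 without any HepaRG array, 1745 without LX2 coculture replicate 3). In LX2, 0 calls became 1 with a floor of 0.02 and 0 to 228 without single arrays (1 without LX2 coculture replicate 2, 228 without replicate 3), and for the difference 2 and 0 to 436 (436 without LX2 coculture replicate 3). Between lines, 4251 became 2076 with probes above background on all arrays, 6450 by probe, 12000 from the compared groups alone, and 3240 to 12013 without single arrays (3240 without LX2 alone replicate 1, 12013 without LX2 coculture replicate 3). The correlation of 0.165 became 0.02 after normexp, 0.312 without the filter, -0.132 with the slide block, and -0.0787 to 0.306 without single arrays (HepaRG coculture replicates 2 and 1).

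With 11 arrays, calls in HepaRG (1745), LX2 (228) and for the difference (436) became 710, 42 and 100 after normexp, 200, 6 and 19 with median scaling, 758, 39 and 89 from the authors' table, 821, 0 and 0 with the replicate block, 117, 7 and 69 at 2-fold, 704, 60 and 109 at an adjusted p under 0.01, and 411, 0 and 358 on slide 1, and 0 for each on slide 2. Quantile normalization gave 122 in LX2 and 179 for the difference, the compared groups alone 819 in HepaRG and 17 in LX2, and for the difference probes above background on all arrays gave 257 and a floor of 0.005 gave 281. Without single arrays the counts were 1166 to 1529 in HepaRG, 84 to 242 in LX2 (84 and 105 without LX2 coculture replicates 2 and 1, 143 without LX2 alone replicate 1) and 182 to 415 for the difference (182 and 190 without LX2 coculture replicates 2 and 1, 229 and 238 without LX2 alone replicates 1 and 2, 250 without HepaRG alone replicate 1). Between lines, 12013 became 19576 by probe, 6066 at 2-fold and 6543 on slide 2. The correlation of 0.198 became 0.276 with the replicate block and 0.0412 to 0.269 without single arrays (LX2 coculture replicate 1 and alone replicate 3), and 0.107 without LX2 alone replicate 1. Arrays with the same number were not treated as paired, since the labels state no pairing. Deviations from the group means correlated at -0.408 to 0.348 in 5 pairs of 1 line with the same number. Within a slide, arrays with the same number correlated at a median of 0.214 and others at 0.209. Such deviations from means of so few arrays are tied to each other, so these values cannot exclude pairing. With 12 arrays the LX2 median of the cholesterol list (-0.967) lay between -1.51 and 0.138 without single arrays and the median difference of the cell cycle list (0.728) between -0.232 and 1.24, and both reversed without LX2 coculture replicate 3. Over other settings, named genes with 11 arrays were on the same side of the threshold 3156 times, weaker 1000, stronger 4 and reversed 0 (12 arrays: 225, 101, 0 and 0), and lists 1036, 51, 17 and 0 (12 arrays: 1062, 86, 26 and 2). On 11 arrays 70 to 81.7% of probes were well above background, and 55.6% on LX2 coculture replicate 3, so changes of dim genes depend on the floor.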

Other observations

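The tests of explanations and the genes named in this part were chosen after the results had been seen.

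Several genes of secreted proteins and receptors outside the lists were called higher in both lines: the hypoxia-induced hormone stanniocalcin STC1, the activin subunit INHBB, the oncostatin M receptor OSMR, the cytokine-like enzyme NAMPT, the collagen processing protein PCOLCE2 and the peptide amidating enzyme PAM (0.21 to 0.95 in HepaRG and 0.34 to 0.94 in LX2). With them rose DDIT4, an inhibitor of mTOR signalling, the glycogen enzymes GYS1 and GBE1, the platelet phosphofructokinase PFKP and FAM162A. Lower in both were the matrix Gla protein MGP, the activin antagonist follistatin FST, the heparan sulfatase SULF2, the small heat shock protein CRYAB, the mitochondrial acyltransferase CPT1A and the stress protein NUPR1. In opposite directions went thrombomodulin THBD (0.77 in HepaRG, -0.58 in LX2), HSD17B2, which inactivates oestradiol and testosterone (0.57 and -0.58), MT1F (0.61 and -0.33), ABTB3 (0.60 and -0.36), BORCS7 (0.10 and -0.12), and the other way RCAN2 (-0.30 and 0.66) and WFS1 (-0.27 and 0.27).

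Hypoxia and glycolysis genes rose in both lines, with medians of 0.633 and 0.646. The slides are argued against by the lowest of the 4 medians within a slide and line, 0.606. For RNA of the other line, 33.3% of the called members started at or above the other line's level, below the bound of 50% set for this test, so it did not argue against that source, but 100% of them needed a larger share than the upper quartile shown by the other line's abundant genes (0.18% in HepaRG and 0.00663% in LX2), which does. Lower oxygen in the coculture vessel, from more cells or the insert, and signals between the lines may each account for the rise, and the design, with no empty insert and no second culture of the same line, leaves these untested.

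The rise of CYP1A1 in HepaRG led to the hypothesis that the aryl hydrocarbon receptor was more active in coculture. Of 6 other known targets tested, 4 were called higher, CYP1B1 (1.04), CYP1A2 (0.92), ALDH3A1 (0.66) and TIPARP (0.44), and UGT1A6 (-0.07) and CYP2S1 (-0.14) were not called (camera p = 0.000921, and p = 0.0115 with an estimated correlation). Of the 3 targets whose values had not been seen when the list was written 1 was called, ALDH3A1, so the number of targets is too small to tell whether the receptor may account for the rise.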
